A study of Homo sapiens with 42 samples.

How the data were processed

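PolyA RNA was pulled down and made into libraries with TruSeq chemistry and a modified final PCR with KAPA HiFi, per the labels. Cells with the hairpin were kept by hygromycin selection, and cells with an RPL3L construct were sorted by their BV421 signal, the channel of EBFP2. Nuclear RNA was sequenced without polyA selection or rRNA depletion, per the labels. The submitters' processing notes name bcl2fastq 2.19, kallisto, Bowtie and bedtools, the last 3 without versions, and do not state which of them made which table. The index, annotation and genome build behind the values are not given in the sources used here.

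The authors deposited 1 table of TPM per gene, used as the unit it states, since every library summed to 1000000 TPM. They also deposited counts per rRNA region of a 45S pre-rRNA reference. Whether a count is a read or a read pair is not stated. The TPM table held 60612 entries, of which 6 were construct sequences left out of the tests and 60606 were genes. All value columns of both tables were matched to a labelled library, leaving 0 unmatched. Raw reads were not used here, so alignment, depth and sequence variants were not checked.

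TPM were taken to log2 with a pseudocount of 1. Genes with a mean TPM of at least 1 over the 30 whole-cell libraries were tested, 14426 in all. limma fitted 1 model over the 10 groups (lmFit, contrasts.fit, eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment over genes within a comparison and a threshold of 0.05. A second model held the library kind as a term. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. fry was run beside camera; it tests whether a list moves on balance and does not compare it with other genes. Of 33 lists with 1105 symbols, 6 symbols were absent from the table, and the 28 lists with at least 5 tested genes were tested. Gene positions, exons and residues came from GRCh38 and GENCODE 29, which was not compared with the annotation behind the TPM.

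Named genes followed a fixed rule. A gene had an adjusted p under 0.05, a symbol of a protein-coding or named non-coding gene, a mean of at least 5 TPM in the higher group, and every library of 1 group above every library of the other. Genes were ranked by the size of the log2 fold change, with the first 10 each way for the comparisons among shScramble, shRPL3 and RPL3L-WT, and the first 5 each way for variants against RPL3L-WT and for D308N against D308V. Up to 4 members of each described list were added, and RPL3 and RPL3L in every comparison. The text names those of them whose call held under the alternatives other than 2 groups only, or says where it was lost. Some genes under the rule are not reported here. Others were mostly snoRNAs, mitochondrial tRNAs and small nuclear RNAs, whose short transcripts share sequence.

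Nuclear rRNA regions were compared as ratios within a library. An exact permutation test over all 10395 groupings of 12 libraries into 6 pairs compared the spread between groups with that within them, with Benjamini-Hochberg adjustment over 7 ratios. Shared controls were handled by simulation: the fitted spreads gave the correlation and covariance that variants show through common RPL3L-WT libraries alone. Expected overlaps were those of independent sets of the same sizes, and shared controls raise them too.

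The fit was tried on values simulated from the data's gene means, residual spread and kind difference. Of 14426 genes, 200 were changed by 0.5, 1 or 2 (log2). For shRPL3 against shScramble it recovered 41.8, 86.6 and 93.9% with 2 false calls, and with the kind term 68.7, 92.5 and 93.9% with 7. For D308N against RPL3L-WT this was 43.3, 80.6 and 93.9% with 27, and with the kind term 59.7, 91.0 and 95.5% with 9. More genes passed in the data, so the false calls do not carry over. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.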

Results

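AC16 is a human cell line with some cardiomyocyte features. The series measured what followed when a doxycycline-induced hairpin lowered RPL3, a protein of the large ribosomal subunit, and when cells with that hairpin also carried a construct for RPL3L, the paralog found mainly in heart and skeletal muscle. PolyA-selected RNA from whole cells was sequenced in 30 libraries. They fall into 10 groups of 3: a scrambled hairpin (shScramble), the RPL3 hairpin alone (shRPL3), the RPL3 hairpin with wild-type RPL3L (RPL3L-WT), and the RPL3 hairpin with RPL3L carrying P291L, G27D, R161W, T189M, D308N, D308V or R343W. Doxycycline was given at 1 ug/ml. A separate set of 12 libraries measured rRNA regions in nuclear RNA from 6 of these lines with 2 libraries each. The whole-cell values were TPM, which keep no depth, so the depth of those libraries is unknown. The nuclear libraries held 8094182 to 14698375 counts in the rRNA regions. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between samples. Values below are means ± SD of 3 libraries unless stated, and fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low TPM. Genes that share sequence with paralogs, pseudogenes or host genes, such as RPL3 and its pseudogene RPL3P4, snoRNAs, mitochondrial tRNAs and readthrough genes, have uncertain values.

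RPL3 lies on chromosome 22 at 39312882 to 39320389 on the minus strand (GRCh38, GENCODE 29, ENSG00000100316.15) and has 10 exons and 403 codons. RPL3L lies on chromosome 16 at 1943974 to 1957606 on the minus strand (ENSG00000140986.7) and has 10 exons and 407 codons. The reference protein carried the first residue of all 7 variants, in exon 2 for G27D, exon 4 for R161W, exon 5 for T189M, exon 7 for P291L, D308N and D308V, and exon 8 for R343W. RPL3 was at 1570.2 ± 38.8 TPM in shScramble and 536 ± 35.2 TPM in shRPL3, a log2 fold change of -1.55 (SE 0.19, adjusted p = 6.22e-07). It was at 519 ± 134 TPM in RPL3L-WT, 674 ± 14.2 in P291L, 633 ± 159 in G27D, 1438 ± 334 in R161W, 942 ± 263 in T189M, 695 ± 17.5 in D308N, 569 ± 1.42 in D308V and 730.2 ± 6.62 in R343W. R161W was thus near the level of shScramble, and its libraries 1 to 3 held 1059, 1686 and 1570.1 TPM.

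RPL3L was at 0.0296 ± 0.0286 TPM in shScramble, where it is all but silent. Its level was 3190.0 ± 535 TPM in RPL3L-WT, 4295 ± 38.3 in P291L, 4002 ± 324 in G27D, 3031 ± 351 in R161W, 2463 ± 513 in T189M, 5116 ± 143 in D308N, 2854 ± 166 in D308V and 2622 ± 125 in R343W. Replicate 3 of shRPL3, a line without an RPL3L construct, held 121 TPM against 0.029 and 0.0353 TPM in replicates 1 and 2. The log2 fold change of RPL3L between shRPL3 and shScramble was 2.30 (adjusted p = 0.0772), 3.45 without shRPL3 1 and 3.45 without shRPL3 2, both past the threshold, and 0.00 without shRPL3 3. The same library widened the spread of RPL3L, and no variant differed from RPL3L-WT in RPL3L past the threshold. With that library left out and the library kind in the model, the log2 difference from RPL3L-WT was 0.22 in G27D, -0.18 in R161W, -0.38 in T189M, 0.47 in D308N, -0.38 in D308V and -0.50 in R343W, all past the threshold.

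**Figure D1:**
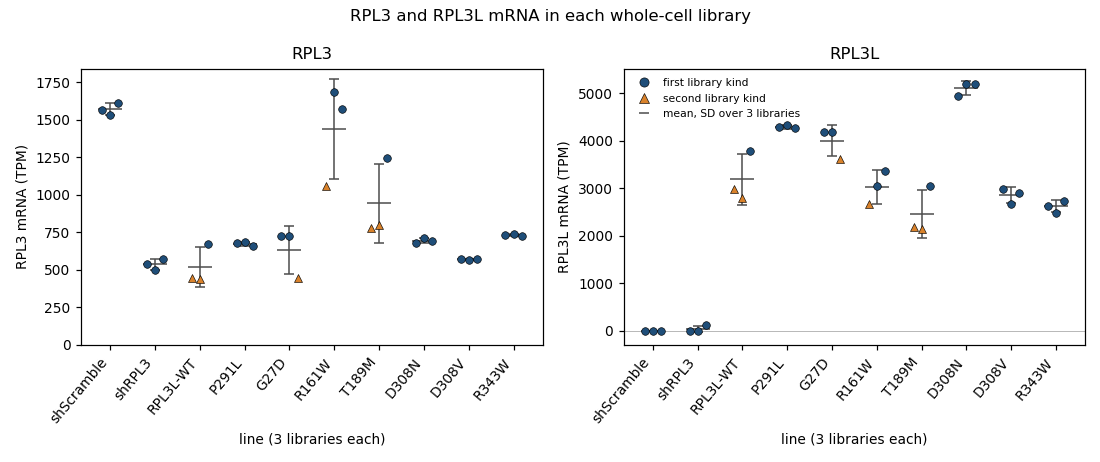
TPM of RPL3 and RPL3L in each of the 30 whole-cell libraries, by group, with the mean and SD of each group and the 2 library kinds marked. RPL3 averaged 536 TPM in shRPL3 and 1438 TPM in R161W, and RPL3L reached 121.3 TPM in 1 of the 3 shRPL3 libraries.

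The libraries were of 2 kinds that the labels do not name. On the levels of 511 pseudogenes, RPL3L-WT 1 and 2, G27D 3, R161W 1 and T189M 1 and 2 stood apart from the other 24 libraries, with a gap of 16 along the first principal component against 1.43 for the next widest gap. These 6 libraries form the second kind. EBFP2 and rtTA3, which the RPL3L construct also encodes, stood in a ratio of 1.431 to 1.574 in them and of 0.9705 to 1.0524 in the 18 construct libraries of the first kind. Between the kinds 8343 genes differed past the threshold, and 1779 of 11487 protein-coding genes were higher and 5500 lower in the second. RPL3L-WT, G27D, R161W and T189M hold both kinds. Comparisons with them are given pooled and within kinds, meaning with a kind term in limma. This term, added after the data were seen, is a shift fitted on these groups. Other groups lack the second kind, so only 1 RPL3L-WT library is of their kind. T189M has the RPL3L-WT mix, so fold changes between them cannot move. Brackets after a gene give log2 fold changes, pooled first. List counts are of genes past the threshold over all 14426 tested. The adjusted p of a list is from camera with a preset correlation. List medians and means are log2 fold changes.

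**Figure D2:**
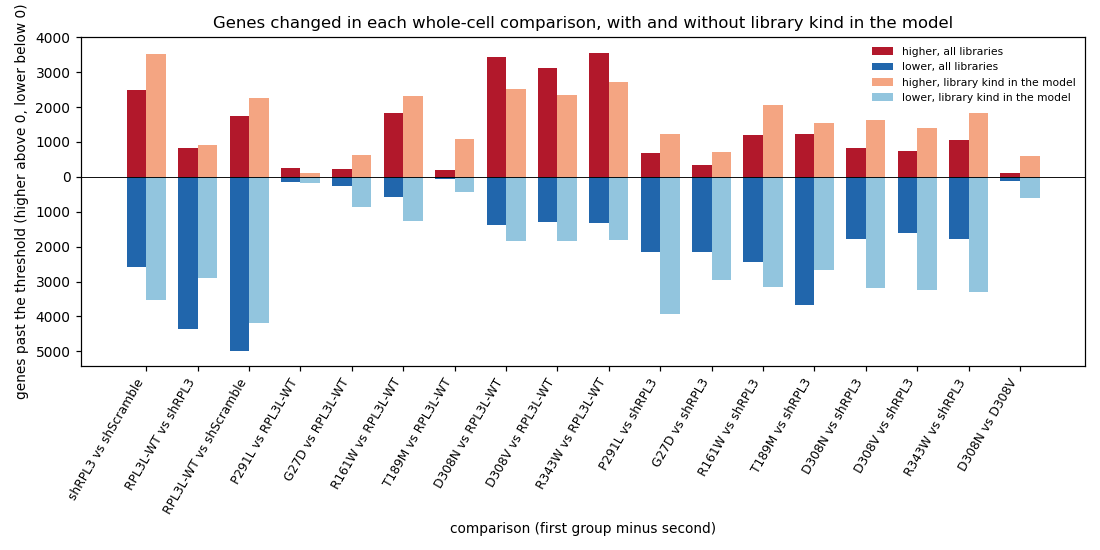
Number of genes higher and lower past an adjusted p of 0.05 (limma) in each of 18 comparisons, pooled and with the library kind in the model. P291L against RPL3L-WT had 240 genes higher and 157 lower pooled, and 119 and 167 within kinds.

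The scale of TPM itself differed between groups. The median log2 fold change of all genes tested was -0.19 for RPL3L-WT against shRPL3, -0.18 for RPL3L-WT against shScramble, 0.10, 0.13, 0.11 and 0.13 for R161W, D308N, D308V and R343W against RPL3L-WT, and -0.10, -0.14 and -0.14 for P291L, G27D and T189M against shRPL3. Median-ratio scaling took these shifts to near 0, and list directions below are relative to all other genes unless a median is given. Calls of list tests with a preset correlation were fewer with an estimated correlation: 6 of 16 for shRPL3 against shScramble, 3 of 12 for RPL3L-WT against shRPL3, 8 of 19 for RPL3L-WT against shScramble, and 0 of 3, 4 of 19, 6 of 21, 0 of 15, 6 of 20, 5 of 18 and 2 of 13 for P291L, G27D, R161W, T189M, D308N, D308V and R343W against RPL3L-WT.

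shRPL3 against shScramble asked what loss of RPL3 does by itself. TXNIP, which binds thioredoxin and limits glucose uptake, rose from near silence (5.90, 122 ± 7.46 against 1.06 ± 0.218 TPM). The cytokine gene IL24 (2.73), the secretory chaperone gene SCG5 (2.51), MROH6 (2.21) and GNB3 (2.05) rose too. FABP3, which carries fatty acids, fell most of the named genes (-3.97, 1.44 ± 0.362 against 36.8 ± 1.45 TPM). The desaturase gene SCD (-2.49, 125 ± 4.25 against 707 ± 12.9 TPM) and the sterol sensor gene INSIG1 (-2.35) fell as well. 24 of 25 cholesterol synthesis genes, among them HMGCS1 (-2.36) and MVD (-2.28), fell and 0 rose (24 and 0 adjusted over the list alone, median -1.72, adjusted p = 2.63e-31).

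Genes that build ribosomes moved the other way. 39 of 61 60S assembly factor genes, among them RPF2 (1.24) and RRS1 (1.20), rose and 0 fell (42 and 0 adjusted over the list alone, median 0.38, adjusted p = 4.53e-14). Of 52 40S assembly factor genes, 38, among them NGDN (0.95) and UTP11 (0.91), rose and 0 fell (40 and 0 adjusted over the list alone, median 0.47, adjusted p = 3.45e-15). Among 25 RNA polymerase I and snoRNP genes, 16, among them DKC1 (0.89), rose and 0 fell (16 and 0 adjusted over the list alone, median 0.44, adjusted p = 2.57e-07). Of 46 large-subunit ribosomal protein genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone, median 0.39, adjusted p = 1.59e-07, or adjusted p = 0.247 with an estimated correlation). Among 33 small-subunit ribosomal protein genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.35, adjusted p = 1.52e-06, or adjusted p = 0.231 with an estimated correlation). Of 19 snoRNA host genes, 10, among them SNHG1 (1.64) and GAS5 (1.50), rose and 1 fell (14 and 1 adjusted over the list alone, median 0.60, adjusted p = 4.31e-07, or adjusted p = 0.212 with an estimated correlation).

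18 of 34 interferon response genes, among them OAS3 (-1.45), fell and 1 rose (18 and 2 adjusted over the list alone, median -0.35, adjusted p = 0.000452, or adjusted p = 0.165 with an estimated correlation). Among 13 mitochondrially encoded genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.48, adjusted p = 0.014, or adjusted p = 0.714 with an estimated correlation, adjusted p = 0.0578 with median-ratio scaling). In all, 2487 genes were higher and 2597 lower in shRPL3 than in shScramble (limma), 3520 and 3539 with the kind term, which only lowered the spread here. 7867 genes (54.5%, against 10% by chance) had every library of shRPL3 on one side of every library of shScramble.

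RPL3L-WT against shRPL3 asked what the wild-type paralog does in cells low in RPL3. The heat shock genes HSPA1A (2.18, 2.06 within kinds, 319 ± 35.1 against 69.5 ± 5.16 TPM) and HSPA6 (2.16, 2.31 within kinds), whose products refold proteins, rose. So did CLU (1.91, 1.28 within kinds), an extracellular chaperone gene, and SPP1 (1.62, 1.34 within kinds), which codes for osteopontin. The matricellular gene CCN4 (-1.72, -1.42 within kinds), LRFN4 (-1.63, -1.19 within kinds) and TPGS1 (-1.51, -1.19 within kinds) fell. RPL3 itself was at -0.07, 0.36 within kinds (adjusted p = 0.781 pooled and 7.24e-07 within kinds), a turn in sign that followed the library kind. 8 of 21 cytosolic heat shock genes, among them HSPA1A (2.18, 2.06 within kinds), rose and 0 fell (9 and 0 adjusted over the list alone, median 0.18, adjusted p = 9.48e-10). Within kinds, 11 rose and 2 fell (median 0.15, adjusted p = 3.46e-08). Of 16 muscle contractile and cardiac genes, 5, among them ANKRD1 (1.25, 1.36 within kinds) and CNN1 (1.22, 0.87 within kinds), rose and 2 fell (5 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.00325). Within kinds, 5 rose and 2 fell (median 0.01, adjusted p = 0.00916, or adjusted p = 0.101 with an estimated correlation).

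Among 19 snoRNA host genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.70, adjusted p = 0.000215, or adjusted p = 0.511 with an estimated correlation). Within kinds, 12 fell and 0 rose (median -0.31, adjusted p = 1.92e-06). 33 of 46 large-subunit ribosomal protein genes fell and 2 rose (37 and 3 adjusted over the list alone, median -0.37, adjusted p = 0.012, or adjusted p = 0.699 with an estimated correlation). Within kinds, 29 fell and 1 rose (median -0.14, adjusted p = 1.5e-05, or adjusted p = 0.369 with an estimated correlation). Of 25 cholesterol synthesis genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone, median -0.33, adjusted p = 0.0148, or adjusted p = 0.676 with an estimated correlation). Within kinds, 8 fell and 1 rose (median -0.13, adjusted p = 0.141). Among 31 glycolysis and hypoxia genes, 21, among them CA9 (-1.57, -1.18 within kinds), fell and 3 rose (22 and 3 adjusted over the list alone, median -0.46, adjusted p = 0.00325, or adjusted p = 0.611 with an estimated correlation). Within kinds, 16 fell and 4 rose (median -0.19, adjusted p = 0.00105, or adjusted p = 0.101 with an estimated correlation). 11 of 13 mitochondrially encoded genes rose and 0 fell (12 and 0 adjusted over the list alone, median 0.84, adjusted p = 1.3e-09, or adjusted p = 0.364 with an estimated correlation). Within kinds, 10 rose and 1 fell (median 0.31, adjusted p = 6.0e-09, or adjusted p = 0.101 with an estimated correlation). Across all genes, 833 were higher and 4359 lower in RPL3L-WT than in shRPL3 by limma, and within kinds 905 and 2901. 5920 genes (41.0%, against 10% by chance) had every library of RPL3L-WT on one side of every library of shRPL3. With median-ratio scaling 1712 genes were higher and 1834 lower. The pooled counts became 514 and 2499 without RPL3L-WT 1 and 507 and 2312 without RPL3L-WT 2.

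Against shScramble, RPL3L-WT cells combined lower RPL3 (-1.62, -1.20 within kinds) with gain of RPL3L (11.59, 11.81 within kinds). TXNIP (5.27, 5.51 within kinds), SCG5 (1.84, 2.12 within kinds), MROH6 (2.18, 2.16 within kinds) and the lipolysis inhibitor gene G0S2 (1.79, 1.64 within kinds) were higher. SCD (-3.56, -3.45 within kinds, 59.6 ± 8.77 against 707 ± 12.9 TPM), FABP3 (-3.36, -3.24 within kinds), the fatty acid desaturase gene FADS2 (-3.13, -2.90 within kinds) and INSIG1 (-3.03, -2.81 within kinds) were lower. Of 25 cholesterol synthesis genes, 24, among them HMGCS1 (-2.96, -2.85 within kinds) and MVD (-2.98, -2.64 within kinds), fell and 0 rose (24 and 0 adjusted over the list alone, median -1.99, adjusted p = 1.66e-25). Within kinds, 24 fell and 0 rose (median -1.79, adjusted p = 4.09e-29). Among 61 60S assembly factor genes, 30 rose and 8 fell (31 and 8 adjusted over the list alone, median 0.21, adjusted p = 5.55e-11). Within kinds, 37 rose and 3 fell (median 0.27, adjusted p = 2.23e-13). Of 46 large-subunit ribosomal protein genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone, median -0.05, mean 0.01, test pointing up, adjusted p = 0.00387, or adjusted p = 0.561 with an estimated correlation, median 0.16 with median-ratio scaling). Within kinds, 36 rose and 2 fell (median 0.24, adjusted p = 1.83e-15, or adjusted p = 0.0633 with an estimated correlation). 

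13 of 21 NF-kB and cytokine genes rose and 1 fell (13 and 1 adjusted over the list alone, median 0.62, adjusted p = 3.17e-08). Within kinds, 12 rose and 0 fell (median 0.35, adjusted p = 6.19e-07). RPL3L-WT had 1745 genes higher and 4985 lower than shScramble (limma), and within kinds 2251 and 4191. 7029 genes (48.7%, against 10% by chance) had every library of RPL3L-WT on one side of every library of shScramble. With median-ratio scaling 3128 genes were higher and 3130 lower.

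The variants were each set against RPL3L-WT. The lines also differed in RPL3, most of all R161W and T189M, so their comparisons span the altered residue and the higher RPL3 together. In P291L the scavenger receptor gene OLR1 (1.43, 1.35 within kinds) and the zinc finger gene PRDM10 (1.26, 1.21 within kinds) were higher and RGS4 (-1.31, -1.17 within kinds), which dampens G protein signals, was lower. RPL3 was at 0.40, -0.02 within kinds, not past the threshold pooled (adjusted p = 0.158), and passed it without RPL3L-WT 3 (0.61). Of 46 ATF4 target genes of the integrated stress response, 3 fell and 1 rose (5 and 3 adjusted over the list alone, median 0.04, mean 0.04, test pointing down, adjusted p = 0.35, median -0.06 with median-ratio scaling). Within kinds, 7 fell and 1 rose (median -0.09, adjusted p = 0.000154, or adjusted p = 0.0954 with an estimated correlation). In all, 240 genes were higher and 157 lower in P291L than in RPL3L-WT (limma), within kinds 119 and 167. 3763 genes (26.1%, against 10% by chance) had every library of P291L on one side of every library of RPL3L-WT. The 2 kinds within RPL3L-WT make 10% an unfair baseline here. With median-ratio scaling 328 genes were higher and 350 lower, and with only the 6 libraries of the 2 groups 5 were higher and 2 lower (unadjusted p under 0.05 in 2876). Leaving out 1 library moved the pooled counts to 49 and 33 without RPL3L-WT 1, 55 and 38 without RPL3L-WT 2, 3360 and 1243 without RPL3L-WT 3, 68 and 41 without P291L 1, 76 and 45 without P291L 2 and 70 and 49 without P291L 3. With the kind term they moved to 64 and 102 without P291L 1, 64 and 89 without P291L 2 and 59 and 101 without P291L 3.

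In G27D the cytokine gene IL24 (1.28, 1.20 within kinds), ZNF519 (1.31, 1.23 within kinds) and AGO4 (1.13, 1.08 within kinds) were higher, and RGS4 (-0.95, -0.88 within kinds) and the iron-binding PIR (-0.90, -0.97 within kinds) were lower. Of 25 cholesterol synthesis genes, 11 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.39, adjusted p = 1.62e-18). Within kinds, 22 fell and 0 rose (median -0.49, adjusted p = 9.55e-30). Among 21 cytosolic heat shock genes, 3 fell and 0 rose (7 and 0 adjusted over the list alone, median -0.20, adjusted p = 8.86e-08). Within kinds, 10 fell and 0 rose (median -0.20, adjusted p = 6.49e-09). 5 of 19 snoRNA host genes, among them GAS5 (0.94, 0.73 within kinds), rose and 0 fell (9 and 1 adjusted over the list alone, median 0.37, adjusted p = 1.28e-06, or adjusted p = 0.219 with an estimated correlation). Within kinds, 8 rose and 0 fell (median 0.22, adjusted p = 8.64e-10). Among 46 large-subunit ribosomal protein genes, 2 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.27, adjusted p = 8.86e-08, or adjusted p = 0.255 with an estimated correlation). Within kinds, 25 rose and 0 fell (median 0.16, adjusted p = 9.08e-19). Across all genes, 223 were higher and 256 lower in G27D than in RPL3L-WT by limma, and within kinds 622 and 868. 1880 genes (13%, against 10% by chance) had every library of G27D on one side of every library of RPL3L-WT. With only the 6 libraries of the 2 groups 1 was higher and 0 lower (unadjusted p under 0.05 in 988). The pooled counts became 72 and 138 without RPL3L-WT 1, 79 and 171 without RPL3L-WT 2, 1221 and 460 without RPL3L-WT 3, 74 and 111 without G27D 1, 78 and 123 without G27D 2 and 661 and 473 without G27D 3. With the kind term they moved to 288 and 552 without G27D 3.

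In R161W, whose RPL3 level was the highest of the variants (1.47, 1.26 within kinds), SCD (1.99, 1.94 within kinds, 238 ± 21.3 against 59.6 ± 8.77 TPM) and the activin subunit gene INHBE (1.99, 1.88 within kinds) were higher, and RGS4 (-1.59, -1.53 within kinds) and IL24 (-1.19, -1.27 within kinds) were lower. 24 of 25 cholesterol synthesis genes rose and 0 fell (24 and 0 adjusted over the list alone, median 0.82, adjusted p = 1.27e-25). Within kinds, 24 rose and 0 fell (median 0.77, adjusted p = 2.08e-29). Of 61 60S assembly factor genes, 14 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.16, adjusted p = 3.41e-12). Within kinds, 28 fell and 1 rose (median -0.18, adjusted p = 2.4e-14). 25 of 46 ATF4 target genes of the integrated stress response, among them PSAT1 (1.12, 0.95 within kinds), rose and 3 fell (29 and 4 adjusted over the list alone, median 0.28, adjusted p = 3.35e-06, or adjusted p = 0.25 with an estimated correlation). Within kinds, 29 rose and 6 fell (median 0.26, adjusted p = 4.43e-07). Of 21 cytosolic heat shock genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone, median -0.12, adjusted p = 6.9e-06). Within kinds, 8 fell and 0 rose (median -0.12, adjusted p = 1.95e-06). Among 10 fibroblast marker genes, 5 rose and 0 fell (7 and 1 adjusted over the list alone, median 0.45, adjusted p = 0.00693, or adjusted p = 0.267 with an estimated correlation). Within kinds, 5 rose and 2 fell (median 0.38, adjusted p = 0.0186, or adjusted p = 0.21 with an estimated correlation). R161W had 1818 genes higher and 587 lower than RPL3L-WT (limma), and within kinds 2326 and 1280. 2915 genes (20.2%, against 10% by chance) had every library of R161W on one side of every library of RPL3L-WT. With median-ratio scaling 1153 genes were higher and 1317 lower, and with only the 6 libraries of the 2 groups 2 were higher and 0 lower (unadjusted p under 0.05 in 2154). Pooled, the counts changed to 1050 and 390 without RPL3L-WT 1, 930 and 413 without RPL3L-WT 2, 3297 and 816 without RPL3L-WT 3, 3097 and 871 without R161W 1, 961 and 338 without R161W 2 and 894 and 397 without R161W 3.

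In T189M the macrophage scavenger receptor gene MSR1 (4.30, 4.30 within kinds, 57.0 ± 18.9 against 1.89 ± 0.588 TPM) stood far above RPL3L-WT, and the replication stress gene ETAA1 (1.13, 1.13 within kinds) was higher. PTX3 (-0.63, -0.63 within kinds), which codes for a secreted pattern recognition protein, was lower. RPL3 was higher (0.85, 0.85 within kinds, adjusted p = 0.0161), a pooled call lost without RPL3L-WT 1 (0.76), RPL3L-WT 2 (0.75) or T189M 3 (0.64). Among 25 cholesterol synthesis genes, 9 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.37, adjusted p = 9.73e-18, or adjusted p = 0.0768 with an estimated correlation). Within kinds, 22 rose and 0 fell (median 0.37, adjusted p = 7.13e-23). 1 of 46 large-subunit ribosomal protein genes fell and 0 rose (4 and 0 adjusted over the list alone, median -0.17, adjusted p = 9.51e-10, or adjusted p = 0.186 with an estimated correlation). Within kinds, 28 fell and 0 rose (median -0.17, adjusted p = 1.6e-28). Of 30 endoplasmic reticulum chaperone genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.18, adjusted p = 1.16e-06, or adjusted p = 0.0779 with an estimated correlation). Within kinds, 16 rose and 0 fell (median 0.18, adjusted p = 4.16e-10). In all, 201 genes were higher and 59 lower in T189M than in RPL3L-WT (limma), within kinds 1084 and 444. 1586 genes (11.0%, against 10% by chance) had every library of T189M on one side of every library of RPL3L-WT. With median-ratio scaling 195 genes were higher and 179 lower, and with only the 6 libraries of the 2 groups 7 were higher and 2 lower (unadjusted p under 0.05 in 778). Leaving out 1 library moved the pooled counts to 96 and 34 without RPL3L-WT 1, 56 and 28 without RPL3L-WT 2, 611 and 104 without RPL3L-WT 3 and 142 and 30 without T189M 2. With the kind term they moved to 640 and 309 without RPL3L-WT 2.

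In D308N, IL24 (3.00, 2.83 within kinds, 86.2 ± 3.09 against 10.2 ± 2.78 TPM) and SCG5 (2.29, 2.01 within kinds) were higher, and PIR (-2.08, -2.22 within kinds) was lower. Of 25 cholesterol synthesis genes, 21 fell and 0 rose (21 and 0 adjusted over the list alone, median -0.67, adjusted p = 3.8e-20). Within kinds, 24 fell and 0 rose (median -0.82, adjusted p = 5.49e-29). Among 21 cytosolic heat shock genes, 17 fell and 0 rose (17 and 0 adjusted over the list alone, median -0.49, adjusted p = 6.43e-16). Within kinds, 16 fell and 0 rose (median -0.43, adjusted p = 8.98e-17). 32 of 61 60S assembly factor genes rose and 1 fell (33 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.000357). Within kinds, 41 rose and 0 fell (median 0.25, adjusted p = 1.32e-09). Of 19 snoRNA host genes, 15 rose and 0 fell (16 and 1 adjusted over the list alone, median 0.73, adjusted p = 4.28e-07, or adjusted p = 0.156 with an estimated correlation). Within kinds, 14 rose and 1 fell (median 0.42, adjusted p = 1.51e-09). Among 46 G2 and M phase genes, 24 fell and 1 rose (24 and 1 adjusted over the list alone, median -0.26, adjusted p = 2.63e-11). Within kinds, 32 fell and 1 rose (median -0.27, adjusted p = 9.67e-18). Across all genes, 3424 were higher and 1368 lower in D308N than in RPL3L-WT by limma, and within kinds 2523 and 1844. 5839 genes (40.5%, against 10% by chance) had every library of D308N on one side of every library of RPL3L-WT. With median-ratio scaling 2258 genes were higher and 2316 lower. The pooled counts became 2051 and 1041 without RPL3L-WT 2.

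D308V changes the same residue. IL24 (3.26, 3.10 within kinds, 104 ± 4.14 against 10.2 ± 2.78 TPM) and SCG5 (2.38, 2.10 within kinds) were higher, and the heat shock genes HSPA1A (-2.40, -2.28 within kinds) and HSPA1B (-1.76, -2.09 within kinds) were lower. RPL3 was at 0.16, -0.27 within kinds, with adjusted p = 0.523 pooled and 1.82e-05 within kinds, where it had turned. Among 25 cholesterol synthesis genes, 16 fell and 0 rose (18 and 0 adjusted over the list alone, median -0.46, adjusted p = 3.06e-11, or adjusted p = 0.125 with an estimated correlation). Within kinds, 21 fell and 0 rose (median -0.63, adjusted p = 5.25e-20). 17 of 21 cytosolic heat shock genes fell and 0 rose (17 and 0 adjusted over the list alone, median -0.47, adjusted p = 2.57e-17). Within kinds, 15 fell and 0 rose (median -0.49, adjusted p = 1.97e-17). Among 19 snoRNA host genes, 15 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.67, adjusted p = 9.44e-08, or adjusted p = 0.183 with an estimated correlation). Within kinds, 13 rose and 0 fell (median 0.48, adjusted p = 1.03e-10). D308V had 3112 genes higher and 1302 lower than RPL3L-WT (limma), and within kinds 2335 and 1832. 5674 genes (39.3%, against 10% by chance) had every library of D308V on one side of every library of RPL3L-WT. With median-ratio scaling 2211 genes were higher and 2110 lower. Pooled, the counts changed to 1975 and 938 without RPL3L-WT 1 and 1847 and 964 without RPL3L-WT 2.

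In R343W the matrix metalloproteinase gene MMP3 (3.31, 3.32 within kinds, 14.6 ± 0.342 against 0.576 ± 0.0849 TPM) and IL24 (2.58, 2.42 within kinds) were higher. RPL3 was at 0.52, 0.09 within kinds and not past the threshold there (adjusted p = 0.0332 pooled). That call was lost without RPL3L-WT 1 (0.42), RPL3L-WT 2 (0.42), R343W 1 (0.52), R343W 2 (0.51), R343W 3 (0.53). Of 21 cytosolic heat shock genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.39, adjusted p = 5.19e-12). Within kinds, 16 fell and 0 rose (median -0.30, adjusted p = 4.22e-12). Among 19 snoRNA host genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.68, adjusted p = 1.6e-05, or adjusted p = 0.391 with an estimated correlation). Within kinds, 12 rose and 1 fell (median 0.41, adjusted p = 1.1e-07). Of 38 lysosome and autophagy genes, 18, among them GPNMB (2.11, 2.10 within kinds), rose and 1 fell (23 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.00412, or adjusted p = 0.578 with an estimated correlation). Within kinds, 14 rose and 8 fell (median 0.09, adjusted p = 0.0633). 8 of 16 muscle contractile and cardiac genes, among them CNN1 (-1.90, -1.55 within kinds), fell and 3 rose (8 and 3 adjusted over the list alone, median -0.22, adjusted p = 0.000507). Within kinds, 8 fell and 4 rose (median -0.15, adjusted p = 0.00044). Of 10 fibroblast marker genes, 6, among them DCN (-1.52, -1.91 within kinds), fell and 2 rose (7 and 2 adjusted over the list alone, median -0.41, adjusted p = 0.000202, or adjusted p = 0.282 with an estimated correlation). Within kinds, 8 fell and 1 rose (median -0.57, adjusted p = 4.05e-06). Among 25 cholesterol synthesis genes, 4 fell and 1 rose (3 and 1 adjusted over the list alone, median -0.05, adjusted p = 0.0136, or adjusted p = 0.578 with an estimated correlation). Within kinds, 14 fell and 1 rose (median -0.25, adjusted p = 3.89e-07). In all, 3536 genes were higher and 1326 lower in R343W than in RPL3L-WT (limma), within kinds 2713 and 1814. 5767 genes (40.0%, against 10% by chance) had every library of R343W on one side of every library of RPL3L-WT. With median-ratio scaling 2337 genes were higher and 2266 lower. Leaving out 1 library moved the pooled counts to 2187 and 975 without RPL3L-WT 2.

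The variants were also set against shRPL3, the line with the RPL3 hairpin and no RPL3L construct. shRPL3 also held less of the hairpin construct, with its TetR at 449.8 ± 18.6 TPM against means of 725 to 1085 TPM in the lines with RPL3L and 1304 TPM in shScramble, and 1 of its libraries held RPL3L. R161W and T189M also had more RPL3 than shRPL3. Of the 25 cholesterol synthesis genes, 11 fell and 0 rose in P291L (12 and 0 adjusted over the list alone, median -0.20, adjusted p = 0.00559, or adjusted p = 0.499 with an estimated correlation). 23 fell and 0 rose in G27D (23 and 0 adjusted over the list alone, median -0.70, adjusted p = 2.32e-18), or 23 and 0 within kinds (median -0.63, adjusted p = 6.74e-21). 20 rose and 0 fell in R161W (24 and 0 adjusted over the list alone, median 0.54, adjusted p = 2.54e-16), or 24 and 0 within kinds (median 0.62, adjusted p = 6.16e-22). 2 rose and 1 fell in T189M (2 and 0 adjusted over the list alone, median 0.08, adjusted p = 0.0129, or adjusted p = 0.529 with an estimated correlation), or 14 and 0 within kinds (median 0.26, adjusted p = 2.47e-08). 23 fell and 0 rose in D308N (23 and 0 adjusted over the list alone, median -0.98, adjusted p = 1.39e-28). 22 fell and 0 rose in D308V (24 and 0 adjusted over the list alone, median -0.79, adjusted p = 9.6e-21). 11 fell and 0 rose in R343W (14 and 0 adjusted over the list alone, median -0.35, adjusted p = 5.83e-07, or adjusted p = 0.364 with an estimated correlation).

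Of the 21 cytosolic heat shock genes, 11 rose and 0 fell in T189M (13 and 0 adjusted over the list alone, median 0.38, adjusted p = 8.12e-09), or 12 and 2 within kinds (median 0.23, adjusted p = 5.91e-08). 6 rose and 1 fell in P291L (7 and 1 adjusted over the list alone, median 0.12, adjusted p = 5.9e-06). 5 rose and 1 fell in G27D (7 and 1 adjusted over the list alone, median 0.00, adjusted p = 0.000181), or 7 and 4 within kinds (median 0.01, adjusted p = 0.0166, or adjusted p = 0.295 with an estimated correlation). 6 rose and 2 fell in R161W (6 and 2 adjusted over the list alone, median 0.08, adjusted p = 0.0059), or 7 and 4 within kinds (median -0.01, mean 0.19, test pointing up, adjusted p = 0.0812). 13 fell and 0 rose in D308V (14 and 0 adjusted over the list alone, median -0.30, adjusted p = 2.92e-05). 9 fell and 1 rose in D308N (12 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.00899). For the 19 snoRNA host genes, 14 fell and 0 rose in R161W (16 and 0 adjusted over the list alone, median -0.79, adjusted p = 5.71e-10, or adjusted p = 0.0888 with an estimated correlation), or 15 and 0 within kinds (median -0.57, adjusted p = 3.61e-13). 16 fell and 0 rose in T189M (16 and 0 adjusted over the list alone, median -0.65, adjusted p = 6.47e-07, or adjusted p = 0.217 with an estimated correlation), or 14 and 0 within kinds (median -0.40, adjusted p = 9.02e-10). For the 46 G2 and M phase genes, 31 fell and 0 rose in D308N (41 and 0 adjusted over the list alone, median -0.44, adjusted p = 2.45e-19). 32 fell and 0 rose in D308V (37 and 0 adjusted over the list alone, median -0.46, adjusted p = 1.42e-20). Fibroblast markers, which these cells express themselves, and markers of library quality were compared as well. In shScramble the fibroblast markers ranged from PDGFRA at 2.42 TPM to VIM at 3476 TPM. For the 10 fibroblast marker genes, 5 fell and 0 rose in D308N (7 and 1 adjusted over the list alone, median -0.37, adjusted p = 0.000533, or adjusted p = 0.142 with an estimated correlation). 5 fell and 0 rose in D308V (5 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.00908, or adjusted p = 0.313 with an estimated correlation). 6 fell and 1 rose in R343W (6 and 3 adjusted over the list alone, median -0.70, adjusted p = 0.00168, or adjusted p = 0.364 with an estimated correlation). 3 rose and 1 fell in R161W (4 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.0323, or adjusted p = 0.361 with an estimated correlation), or 6 and 2 within kinds (median 0.27, adjusted p = 0.00381, or adjusted p = 0.12 with an estimated correlation). For the 17 replication-dependent histone genes, whose RNAs lack a polyA tail, 5 fell and 0 rose in D308N (6 and 0 adjusted over the list alone, median -0.50, adjusted p = 0.00269, or adjusted p = 0.0566 with an estimated correlation). 4 fell and 0 rose in D308V (4 and 0 adjusted over the list alone, median -0.30, adjusted p = 0.143). Neither list passed the threshold in G27D, where 2 rose and 5 fell of the fibroblast markers (adjusted p = 0.315) and 0 rose and 3 fell of the histone genes (adjusted p = 0.443), and of 6 nuclear-retained RNAs 2 rose and 1 fell (adjusted p = 0.153).

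Across all genes, the numbers higher and lower than in shRPL3 were 673 and 2161 in P291L, 348 and 2159 in G27D, 1206 and 2431 in R161W, 1215 and 3681 in T189M, 827 and 1782 in D308N, 748 and 1602 in D308V, 1041 and 1795 in R343W (limma). With the kind in the model they were 1229 and 3942 in P291L, 724 and 2963 in G27D, 2063 and 3147 in R161W, 1551 and 2678 in T189M, 1614 and 3199 in D308N, 1395 and 3232 in D308V, 1827 and 3290 in R343W. With median-ratio scaling they were 1212 and 1221 in P291L, 702 and 876 in G27D, 1638 and 1999 in R161W, 2025 and 2342 in T189M, 1261 and 1549 in D308N, 1157 and 1182 in D308V, 1472 and 1482 in R343W. Leaving out 1 library moved the pooled counts to 493 and 1385 in P291L without P291L 2, 224 and 1240 in G27D without shRPL3 2, 255 and 1134 in G27D without G27D 3, 794 and 2133 in T189M without T189M 2. The groups did not overlap for 7145 in P291L, 5406 in G27D, 5711 in R161W, 5859 in T189M, 6353 in D308N, 6395 in D308V, 6591 in R343W, in numbers of genes, against 10% of the 14426 by chance.

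D308N against D308V compared 2 changes of 1 residue in lines that also differed in RPL3L, at 5116 ± 143 and 2854 ± 166 TPM. With the library kind in the model and shRPL3 3 left out that was a log2 difference of 0.84, past the threshold. The skin-expressed gene DMKN (1.38) and the elongation factor gene EEF1A2 (0.85) were higher in D308N, and the activin subunit gene INHBA (-1.19), the heme oxygenase gene HMOX1 (-1.03), the activin-binding gene FST (-1.03) and RGS4 (-0.97) were lower. 4 of 25 cholesterol synthesis genes fell and 0 rose (5 and 0 adjusted over the list alone, median -0.24, adjusted p = 2.13e-11, or adjusted p = 0.324 with an estimated correlation). Across all genes, 112 were higher and 125 lower in D308N than in D308V by limma, and 587 and 604 with the kind term, which only lowered the spread here. 3874 genes (26.9%, against 10% by chance) had every library of D308N on one side of every library of D308V. With median-ratio scaling 145 genes were higher and 281 lower. The pooled counts became 29 and 54 without D308N 2, 28 and 67 without D308N 3, 58 and 78 without D308V 1, 26 and 70 without D308V 2 and 39 and 56 without D308V 3. With the kind term they moved to 314 and 352 without D308N 2, 279 and 391 without D308N 3, 257 and 438 without D308V 2 and 325 and 340 without D308V 3.

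**Figure D3:**
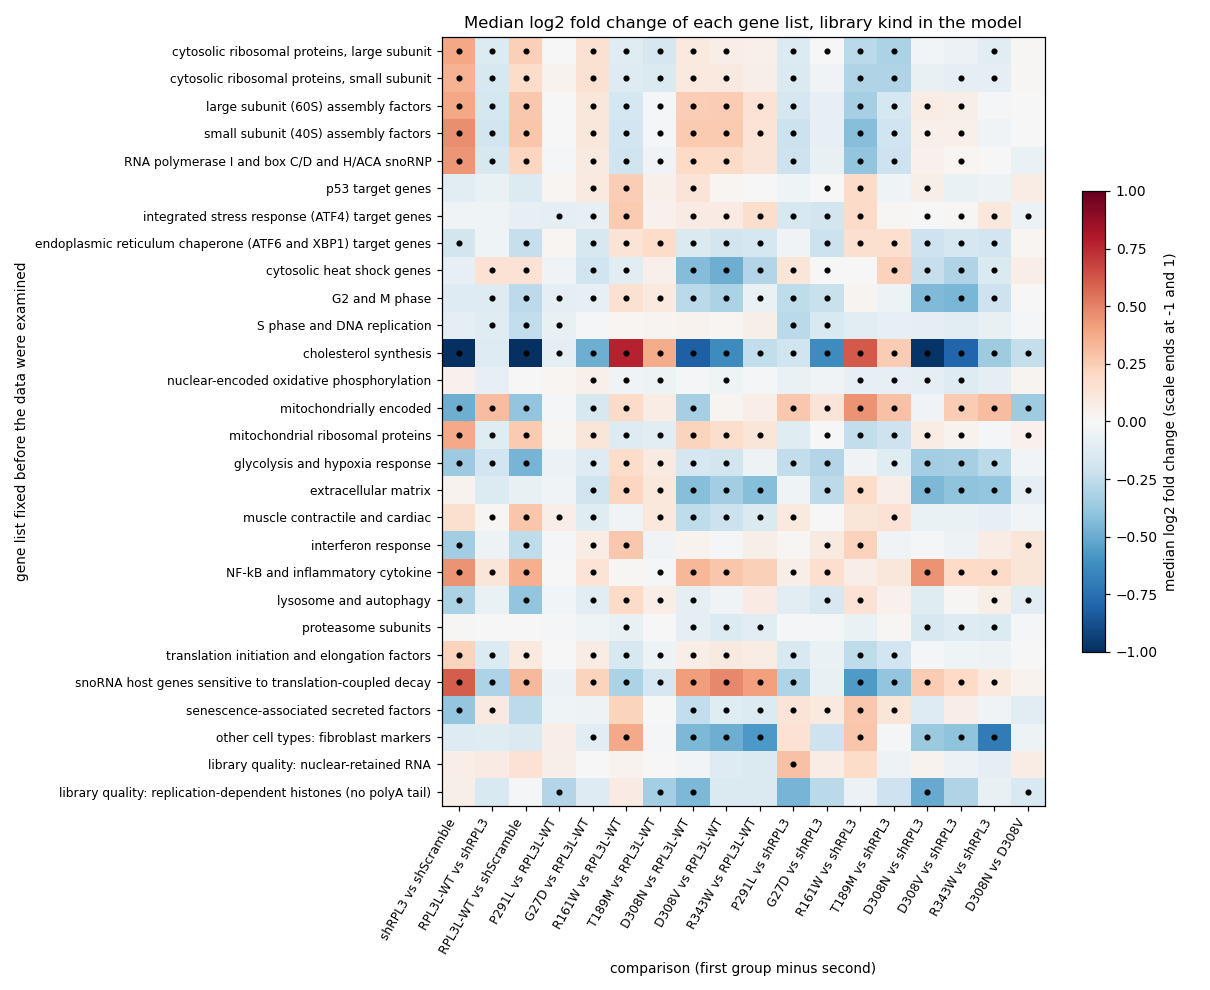
Median log2 fold change of 28 gene lists in 18 comparisons with the library kind in the model, as colour, with a dot where the list test passed an adjusted p of 0.05. Cholesterol synthesis genes had a median of -0.82 in D308N and 0.77 in R161W against RPL3L-WT.

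The change from RPL3L-WT to each variant was set beside the change from shScramble to shRPL3 across the 14426 genes, which are not independent replicates. Pearson's r, ± a standard error from leaving out each of the 12 libraries in turn, was -0.010 ± 0.033 in P291L (0.012 ± 0.028 within kinds), 0.182 ± 0.058 in G27D (0.214 ± 0.034 within kinds), -0.294 ± 0.056 in R161W (-0.307 ± 0.045 within kinds), -0.19 ± 0.039 in T189M (-0.19 ± 0.033 within kinds), 0.284 ± 0.065 in D308N (0.361 ± 0.044 within kinds), 0.24 ± 0.054 in D308V (0.301 ± 0.038 within kinds) and 0.083 ± 0.025 in R343W (0.114 ± 0.011 within kinds). Spearman's rho was 0.02 in P291L, 0.29 in G27D, -0.36 in R161W, -0.32 in T189M, 0.35 in D308N, 0.31 in D308V and 0.12 in R343W, and within kinds 0.06 in P291L, 0.35 in G27D, -0.39 in R161W, -0.32 in T189M, 0.45 in D308N, 0.40 in D308V and 0.16 in R343W. IL24 and SCG5, higher in shRPL3 than in shScramble, were also higher in D308N and D308V than in RPL3L-WT. SCD, lower in shRPL3 than in shScramble, was higher in R161W than in RPL3L-WT.

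Variants share 3 RPL3L-WT libraries, which alone makes their changes alike. Covariance and r stand beside values simulated with shared controls and no shared effect, and overlaps beside those of independent sets, all within kinds. Of the 21 pairs, r was above simulation in 5 and below in 16, and covariance above in 10 and below in 11. Effects of 1 variant alone lower r, so an r below simulation does not make a pair unlike. The pairs below were chosen after values were seen. For D308N and D308V r was 0.739 against 0.595 simulated, the covariance 0.108 against 0.0419 (a difference of 0.0663), and 1715 genes were higher in both against 408 expected and 1248 lower in both against 234, with 8 opposite. For D308V and R343W r was 0.691 against 0.592 simulated, the covariance 0.11 against 0.0417 (a difference of 0.0686), and 1531 genes were higher in both against 439 expected and 1029 lower in both against 230.4, with 72 opposite. For G27D and D308N r was 0.648 against 0.543 simulated, the covariance 0.0688 against 0.0353 (a difference of 0.0335), and 526 genes were higher in both against 109 expected and 726 lower in both against 111, with 8 opposite. For D308N and R343W r was 0.562 against 0.598 simulated, the covariance 0.0866 against 0.0419 (a difference of 0.0447), and 1330 genes were higher in both against 474 expected and 806 lower in both against 232, with 208 opposite. For R161W and T189M r was 0.501 against 0.483 simulated, the covariance 0.0513 against 0.0281 (a difference of 0.0233), and 659 genes were higher in both against 175 expected and 263 lower in both against 39.4, with 39 opposite. For R161W and D308N r was 0.129 against 0.54 simulated, the covariance 0.0164 against 0.0349 (a difference of -0.0185), and 304 genes were higher in both against 407 expected and 173 lower in both against 164, with 1073 opposite. The 3 controls were not divided between the variants of a pair, so part of any excess can come from them.

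Nuclear libraries asked if rRNA processing differed between shRPL3, RPL3L-WT and 4 variants. 18S goes into the small ribosomal subunit, and 28S and 5.8S into the large one, which holds RPL3. All 3 are cut from 1 precursor, without its spacers ETS5, ITS1, ITS2 and ETS3. Over 2 libraries each, the ratio of 28S to 18S counts was 2.47 ± 0.0034 in RPL3L-WT, 2.01 ± 0.010 in shRPL3, 2.04 ± 0.0913 in G27D, 2.49 ± 0.0947 in R161W, 2.65 ± 0.0687 in T189M and 2.26 ± 0.0258 in D308N. It was thus -18.7% in shRPL3, -17.3% in G27D and -8.29% in D308N relative to RPL3L-WT, and 0.865% in R161W and 7.29% in T189M. Both libraries lay on one side of both RPL3L-WT libraries in shRPL3, G27D, T189M and D308N. Across the 6 groups the ratio differed (exact permutation p = 0.00106, adjusted p = 0.00219). With 28S taken against the sum of all regions, the log2 difference from RPL3L-WT went to -0.12 from -0.30 in shRPL3, to -0.14 from -0.27 in G27D and to 0.019 from 0.10 in T189M. That of R161W (0.012) turned negative there, and without nuclear R161W replicate 1 (-0.026).

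The spacers, relative to the mature RNAs, also varied between the lines. As folds over RPL3L-WT, ETS5 to 18S was 1.37 in shRPL3, 1.87 in G27D, 1.44 in R161W, 1.11 in T189M and 1.99 in D308N (exact permutation p = 0.00183, adjusted p = 0.00256). ITS1 to 18S was 1.57 in shRPL3, 1.89 in G27D, 1.59 in R161W, 1.12 in T189M and 2.10 in D308N (exact permutation p = 0.00106, adjusted p = 0.00219). ITS2, which parts 5.8S from 28S, was at 0.984 in shRPL3, 1.21 in G27D, 1.20 in R161W, 1.26 in T189M and 1.56 in D308N relative to 18S (exact permutation p = 0.00298, adjusted p = 0.00348), and at 1.21 in shRPL3, 1.46 in G27D, 1.19 in R161W, 1.17 in T189M and 1.70 in D308N relative to 28S (exact permutation p = 0.00125, adjusted p = 0.00219), a ratio added after the data were seen. ETS3 to 18S was 2.82 in shRPL3, 3.58 in G27D, 1.40 in R161W, 0.927 in T189M and 1.64 in D308N (exact permutation p = 0.000577, adjusted p = 0.00219). Leaving out 1 library at a time, the log2 difference for ETS3 to 18S was 1.25 to 1.74 in shRPL3, 1.59 to 2.08 in G27D, 0.24 to 0.73 in R161W, -0.36 to 0.14 in T189M and 0.47 to 0.96 in D308N, that of T189M turning without nuclear RPL3L-WT replicate 1, and for ETS5 to 18S it was 0.023 to 0.28 in T189M. The ratio of 5.8S to 18S did not differ past the threshold (exact permutation p = 0.378, adjusted p = 0.378). The 7 tests compared all 6 groups at once, with a smallest possible p of 9.62e-05, and single lines were not tested. The pooled SD within groups was 0.0385 (log2) for 28S to 18S. Counting error was at most 2.15% for ETS3 and 0.573% for the other regions, below the pooled spread between replicates.

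**Figure D4:**
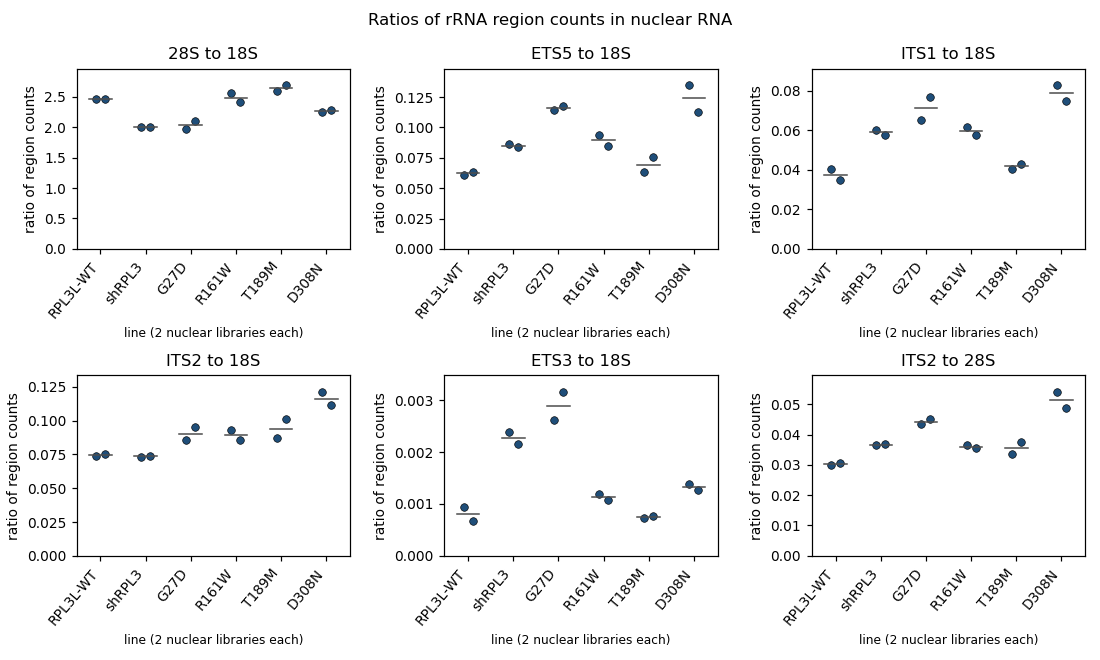
Ratio of the counts of rRNA regions in nuclear RNA for each of 12 libraries, 2 per line, in 6 panels. The ratio of 28S to 18S was 2.47 in RPL3L-WT and 2.01 in shRPL3.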

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

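The tests in this part were chosen only after the results were seen, except that of gene length.

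RPL3L stood at 121.3 TPM in shRPL3 replicate 3, a line with no RPL3L construct, against at most 0.0571 TPM in the other hairpin-only libraries. The construct sequences rtTA3 and EBFP2, which no comparison used, stood at 427.9 and 433.8 TPM in it, against at most 0.217 TPM and at 0. What marked these values is a signal outside the tested genes, or in a line that should lack it, above the level of the control libraries.

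Expression of the endogenous RPL3L gene is argued against by EBFP2 at 433.8 TPM, a sequence only the construct holds. RNA or reads of an RPL3L line in that library is a candidate explanation: its RPL3L to rtTA3 ratio of 0.283 fell in the range of 0.259 to 0.313 of the 18 first-kind RPL3L libraries. Its RPL3L, rtTA3 and EBFP2 were 3.29%, 3.34% and 3.36% of the mean of those lines. Whether this happened in culture, at library preparation or in index reading stays open.

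The whole-cell libraries RPL3L-WT 1 and 2, G27D 3, R161W 1 and T189M 1 and 2 stood apart from the other 24. A difference between the lines is argued against by 4 groups that hold libraries of both kinds. A difference in library preparation or sequencing is a candidate explanation, with an EBFP2 to rtTA3 ratio of at least 1.431 in the 6 against at most 1.0524 in the 18 others with a construct, though 1 vector encodes both. Gene length bias stays open: across protein-coding genes the difference between kinds had a Spearman rho of 0.132 with the length of the longest transcript, which 97.8% of them had. The labels name no batch.

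RPL3 was higher in R161W and T189M than in the other lines with the hairpin. Loss of the hairpin construct is argued against by its TetR at 845.4 TPM or more in their first-kind libraries, within the 690.2 to 1125 TPM of the other RPL3L lines. RPL3L reads counted as RPL3 are argued against by RPL3L of at most 3373 TPM there, below the 4263 TPM or more of P291L, whose RPL3 was 658 to 685 TPM. The library kind is argued against by values within each kind: 1246 TPM or more against at most 737 in the first and 779.7 or more against at most 449 in the second, so at least 1.69 times as high. A weaker hairpin effect or a change in RPL3 transcription or decay in these lines was not tested.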

How the results depend on the processing

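The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except that every alternative with a library kind, and the rRNA ratio ITS2 to 28S, were chosen after seeing the data, as was median-ratio scaling for the gene lists. Of 1708 log2 fold changes past the threshold under the rule for named genes, none turned except with the first library kind only, where 2 did. Their calls were 1695 kept and 13 lost with a pseudocount of 0.1, 1693 kept and 15 lost with 5, 1665 kept and 43 lost with the replicate block, 1533 kept and 175 lost with median-ratio scaling, 1586 kept and 122 lost with the library kind in the model, 1566 kept and 142 lost with shRPL3 replicate 3 left out as well, 1438 kept and 268 lost (and those turned) with the first library kind only, and 1178 kept and 530 lost with 2 groups only. Over all omissions of 1 library, 8288 kept and 1960 lost. The gene counts were within 1.5 times the pooled count with each pseudocount, with no filter on low values, and with a mean TPM of at least 5. With 2 groups only fewer libraries estimate the spread, and counts went up in some comparisons and down in others. RPL3L-WT and T189M keep 1 library each with the first library kind only, as do G27D and R161W with the second. These are assumed to vary like the others. Below stand counts past 1.5 times, values with a changed call or sign, and values without a test that moved by more than the spread between replicates. Their cause was not tested beyond what each choice does by construction.

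With 2 groups only, the numbers of genes changed were 1429 in RPL3L-WT, 5028 in P291L, 422 in G27D, 1579 in R161W, 2007 in T189M, 3940 in D308V against shRPL3, 4395 in RPL3L-WT against shScramble, 7 in P291L, 1 in G27D, 2 in R161W, 9 in T189M, 2210 in D308N, 1993 in D308V, 2278 in R343W against RPL3L-WT and 429 in D308N against D308V. The RPL3 log2 fold changes were 1.47 in R161W, 0.85 in T189M, 0.52 in R343W against RPL3L-WT, 0.33 in P291L, 0.38 in D308N, 0.45 in R343W against shRPL3 and 0.29 in D308N against D308V. Under this choice the RPL3L log2 fold changes were 0.69 in D308N against RPL3L-WT, 9.62 in G27D against shRPL3 and 0.84 in D308N against D308V.

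With an absolute log2 fold change of at least 1 required, the numbers of genes changed were 416 in shRPL3, 798 in RPL3L-WT against shScramble, 231 in RPL3L-WT, 125 in P291L, 74 in G27D, 140 in R161W, 268 in T189M, 135 in D308N, 123 in D308V, 205 in R343W against shRPL3, 27 in P291L, 12 in G27D, 93 in R161W, 13 in T189M, 282 in D308N, 276 in D308V, 366 in R343W against RPL3L-WT and 10 in D308N against D308V.

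With the estimated correlation, the numbers of gene lists past the threshold were 6 in shRPL3, 8 in RPL3L-WT against shScramble, 3 in RPL3L-WT, 2 in P291L, 3 in G27D, 6 in R161W, 2 in T189M, 5 in D308N, 5 in D308V, 1 in R343W against shRPL3, 0 in P291L, 4 in G27D, 6 in R161W, 0 in T189M, 6 in D308N, 5 in D308V, 2 in R343W against RPL3L-WT and 0 in D308N against D308V.

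With the first library kind only, the numbers of genes changed were 2051 in RPL3L-WT, 5481 in P291L, 2973 in T189M, 5103 in D308N, 4908 in D308V, 5388 in R343W against shRPL3, 125 in P291L, 52 in T189M, 3175 in R343W against RPL3L-WT and 1359 in D308N against D308V. There, the RPL3 log2 fold changes were 0.33 in RPL3L-WT, 0.33 in P291L, 0.44 in G27D, 0.38 in D308N, 0.45 in R343W against shRPL3, -0.24 in D308V, 0.12 in R343W against RPL3L-WT and 0.29 in D308N against D308V. The turned genes were MSMO1 (0.032, RPL3L-WT against shRPL3) and SDHC (-0.034, D308N against RPL3L-WT).

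With the library kind in the model, the numbers of genes changed were 1490 in G27D, 1528 in T189M against RPL3L-WT, 5171 in P291L, 4813 in D308N, 4627 in D308V, 5117 in R343W against shRPL3 and 1191 in D308N against D308V. Under this choice the numbers of gene lists past the threshold were 6 in P291L against RPL3L-WT and 15 in R343W against shRPL3. There, the RPL3 log2 fold changes were 0.355 in RPL3L-WT, 0.33 in P291L, 0.42 in G27D, 0.38 in D308N, 0.45 in R343W against shRPL3, -0.27 in D308V, 0.092 in R343W against RPL3L-WT and 0.29 in D308N against D308V. Variant and knockdown changes had r of 0.012 in P291L, 0.361 in D308N, 0.301 in D308V and 0.114 in R343W.

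With the library kind in the model and shRPL3 replicate 3 left out, the numbers of genes changed were 3356 in RPL3L-WT, 4653 in P291L, 4345 in D308N, 4014 in D308V, 4532 in R343W against shRPL3, 1497 in G27D, 3616 in R161W, 1537 in T189M against RPL3L-WT and 1172 in D308N against D308V. Under this choice the RPL3 log2 fold changes were 0.40 in RPL3L-WT, 0.38 in P291L, 0.47 in G27D, 0.42 in D308N, 0.13 in D308V, 0.49 in R343W against shRPL3, -0.27 in D308V against RPL3L-WT and 0.29 in D308N against D308V. There, the RPL3L log2 fold changes were 0.22 in G27D, -0.18 in R161W, -0.38 in T189M, 0.47 in D308N, -0.38 in D308V, -0.50 in R343W against RPL3L-WT and 0.84 in D308N against D308V.

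With the library kind in the model and the estimated correlation, the numbers of gene lists past the threshold were 3 in RPL3L-WT, 1 in P291L, 8 in G27D, 8 in D308V, 0 in R343W against shRPL3, 10 in RPL3L-WT against shScramble and 0 in P291L, 13 in R161W, 7 in T189M, 6 in R343W against RPL3L-WT.

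With the library kind in the model and the replicate block, the numbers of genes changed were 1498 in G27D, 1522 in T189M against RPL3L-WT, 5150 in P291L, 4819 in D308N, 4596 in D308V, 5084 in R343W against shRPL3 and 1163 in D308N against D308V.

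With a mean TPM of at least 5, variant and knockdown changes had r of 0.019 in P291L, 0.279 in G27D and -0.362 in R161W. It was -0.279 in T189M, 0.353 in D308N, 0.309 in D308V and 0.123 in R343W.

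With median-ratio scaling, the numbers of genes changed were 678 in P291L, 760 in G27D against RPL3L-WT, 1578 in G27D against shRPL3 and 426 in D308N against D308V. The numbers of gene lists past the threshold were 5 in P291L against RPL3L-WT. Under this choice the RPL3 log2 fold changes were 0.375 in R343W against RPL3L-WT and 0.44 in P291L, 0.43 in D308N, 0.51 in R343W against shRPL3.

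With the ratio to the sum of all regions, the 28S log2 difference from nuclear RPL3L-WT turned negative in R161W. It was -0.12 in shRPL3, -0.14 in G27D and 0.019 in T189M. In shRPL3 and G27D, ETS5 gave 0.63 and 1.03, ITS1 0.83 and 1.05 and ITS2 0.15 and 0.41.

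With the second library kind only, the numbers of genes changed were 1 in G27D, 54 in R161W, 16 in T189M against RPL3L-WT.

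Leaving out 1 library at a time, the numbers of genes changed were 2819 to 6958 in RPL3L-WT, 1878 to 2206 in P291L, 1389 to 2332 in G27D, 2927 to 6288 in T189M against shRPL3, 82 to 4603 in P291L, 185 to 1681 in G27D, 1291 to 4113 in R161W, 84 to 715 in T189M, 3092 to 6316 in D308N, 2811 to 6169 in D308V, 3162 to 6511 in R343W against RPL3L-WT and 83 to 186 in D308N against D308V (lowest to highest). Over these omissions the numbers of genes changed with the kind in the model were 153 to 253 in P291L, 840 to 1325 in G27D, 949 to 1587 in T189M against RPL3L-WT and 665 to 1136 in D308N against D308V. The RPL3 log2 fold changes were 0.30 to 0.61 in P291L, 0.635 to 1.055 in T189M, 0.34 to 0.65 in D308N, 0.415 to 0.72 in R343W against RPL3L-WT. In the same way, the RPL3L log2 fold changes were 0.004 to 3.45 in shRPL3 against shScramble. Over these omissions the log2 differences from nuclear RPL3L-WT were -0.32 to -0.23 in G27D, -0.026 to 0.051 in R161W for 28S to 18S, 0.023 to 0.28 in T189M, 0.86 to 1.12 in D308N for ETS5 to 18S, 0.80 to 1.04 in G27D for ITS1 to 18S, -0.076 to 0.52 in D308N for 5.8S to 18S, 0.22 to 0.44 in T189M for ITS2 to 18S and 1.25 to 1.74 in shRPL3, 1.59 to 2.08 in G27D, 0.24 to 0.73 in R161W, -0.36 to 0.14 in T189M, 0.47 to 0.96 in D308N for ETS3 to 18S. Variant and knockdown changes had r of -0.022 to 0.014 in P291L and -0.194 to -0.149 in T189M. With the kind in the model r was -0.005 to 0.03 in P291L, -0.313 to -0.257 in R161W and 0.313 to 0.365 in D308N. It was 0.260 to 0.301 in D308V and 0.101 to 0.115 in R343W.

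The replicate block, which takes the replicate number of the labels as a term, moved the number of lists past the threshold only for T189M against RPL3L-WT, to 14 from 15. The replicate numbers did not pair the libraries: for T189M against RPL3L-WT the residuals of libraries with equal numbers had r of 0.191, 0.194 and 0.505, which became -0.078, -0.044 and -0.322 with the library kind removed, and no other comparison had all 3 above 0.1. TPM keeps no depth, so its share in any of these changes is unknown. Planned comparisons of nuclear genes, with their own alternatives, were not run, as the TPM have no nuclear libraries.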

Other observations

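The tests of splits were chosen only after the results were seen, and so were the relations of the snoRNA host and cholesterol synthesis lists with rRNA.

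Few of the genes that mark adult heart muscle were expressed in these cells. The myosin heavy chain genes MYH6 and MYH7, the troponin gene TNNT2 and the cardiac actin gene ACTC1 had means of 0.0273, 0.00449, 0.118 and 0.0875 TPM over the 30 libraries. The most abundant genes of the same list were TPM2 at 1223, TPM1 at 422, MYL9 at 365, TAGLN at 321 and TNNT1 at 129 TPM, while CNN1 stood at 28, ACTA2 at 6.18, MYOCD at 1.09 and DES at 0.218 TPM. Markers of endothelial, epithelial, blood and neural cells had too few tested genes for a list test, with 0, 4, 2 and 4 of 10 tested. The highest of each were TEK at 0.553, KRT18 at 261, CD68 at 124 and TUBB3 at 85.3 TPM, and most others were near 0, such as EPCAM at 0.176, PTPRC at 0.274 and STMN2 at 0.00278 TPM.

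R161W differed from RPL3L-WT in further lists of stress and immune genes. 18 of 47 p53 target genes rose and 2 fell (24 and 3 adjusted over the list alone, median 0.34, adjusted p = 9.53e-05, or adjusted p = 0.267 with an estimated correlation). Within kinds, 22 rose and 2 fell (median 0.25, adjusted p = 0.000505). Of 34 interferon response genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.29, adjusted p = 6.05e-05, or adjusted p = 0.0875 with an estimated correlation). Within kinds, 17 rose and 0 fell (median 0.27, adjusted p = 2.09e-05). D308N against RPL3L-WT lowered transcripts of the mitochondrial genome, which code for respiratory chain subunits. 12 of 13 mitochondrially encoded genes fell and 0 rose (12 and 0 adjusted over the list alone, median -0.84, adjusted p = 8.74e-09, or adjusted p = 0.156 with an estimated correlation). Within kinds, 11 fell and 1 rose (median -0.33, adjusted p = 9.27e-08, or adjusted p = 0.0877 with an estimated correlation). Genes for protein folding in the endoplasmic reticulum were lower in G27D than in RPL3L-WT. Of 30 endoplasmic reticulum chaperone genes, 5 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.12, adjusted p = 1.59e-08). Within kinds, 12 fell and 0 rose (median -0.16, adjusted p = 7.77e-13).

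One hypothesis was that cholesterol synthesis genes follow the RPL3 mRNA level. shScramble, R161W and T189M, whose RPL3 stood apart at 1570.2, 1628 and 1246 TPM in first-kind libraries, also had the 3 highest list means, at 7.22, 6.17 and 5.79 against at most 5.52 in the other lines (log2), which goes with the hypothesis. Since the lines form 2 clusters no r was taken over all 10. Within the 7 others, at 536 to 730.2 TPM of RPL3, the list mean and RPL3 had a Spearman rho of -0.43 (exact permutation p = 0.354) and a Pearson r of -0.305 (exact permutation p = 0.491), with r of -0.366 without the 2 lines farthest from the median. Neither passed the threshold in this narrow range. D308N had the lowest list mean, at -2.76 from shScramble, with RPL3 at 695 TPM, which argues against RPL3 as the only influence. Whether the higher RPL3 of R161W and T189M raised their list stays open.

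The nuclear 28S to 18S ratio was set beside whole-cell list means over 6 lines. The 60S assembly factor list had a Spearman rho of -0.77 (exact permutation p = 0.103, adjusted p = 0.154 over 3 relations) and a Pearson r of -0.661 (exact permutation p = 0.153), with r of -0.688 without the 2 lines farthest from the median. The snoRNA host list had a Spearman rho of -0.77 (exact permutation p = 0.103, adjusted p = 0.154 over 3 relations) and a Pearson r of -0.748 (exact permutation p = 0.113), with r of -0.828 without the 2 lines farthest from the median. For cholesterol synthesis there was a Spearman rho of 0.54 (exact permutation p = 0.297, adjusted p = 0.297 over 3 relations) and a Pearson r of 0.511 (exact permutation p = 0.312), with r of 0.80 without the 2 lines farthest from the median. None passed the threshold, and with 6 lines from the same hairpin background whether the lists follow rRNA processing cannot be told apart from no relation.

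Each set of 6 libraries has 10 splits into 3 and 3, too few for a share under 0.05. In 15 comparisons 1 of the 10 splits, the real one, gave as many genes. The real count and the highest of the others were 5084 and 1 for shRPL3 against shScramble, 5192 and 1 for RPL3L-WT against shRPL3, 6730 and 1 for RPL3L-WT against shScramble, 397 and 0 for P291L against RPL3L-WT, 4792 and 1 for D308N against RPL3L-WT, 4414 and 1 for D308V against RPL3L-WT, 4862 and 1 for R343W against RPL3L-WT, 2834 and 0 for P291L against shRPL3, 2507 and 1 for G27D against shRPL3, 3637 and 0 for R161W against shRPL3, 4896 and 1 for T189M against shRPL3, 2609 and 0 for D308N against shRPL3, 2350 and 0 for D308V against shRPL3, 2836 and 0 for R343W against shRPL3, 237 and 0 for D308N against D308V. In 3 comparisons with RPL3L-WT, 2 of the 10 splits did, the other one following the library kind (for T189M as far as 3 against 3 allows). For G27D against RPL3L-WT, 479 genes stood against 5503 for the split that set RPL3L-WT 1, RPL3L-WT 2, G27D 3 apart, and within kinds 1490 against 1 at most. For R161W against RPL3L-WT, 2405 genes stood against 6140 for the split that set RPL3L-WT 1, RPL3L-WT 2, R161W 1 apart, and within kinds 3606 against 6 at most. For T189M against RPL3L-WT, 260 genes stood against 1566 for the split that set RPL3L-WT 1, RPL3L-WT 2, T189M 2 apart, and within kinds 1528 against 67 at most. A split calling several times the real count points to a structure of the samples.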
